A study of Phaeodactylum tricornutum CCAP 1055/1 with 6 samples.

How the data were processed

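RNA of Phaeodactylum tricornutum cultures was sequenced in 6 libraries, 3 of control and 3 of grazing cultures. According to the labels the cultures held 9 L, were kept at 18 °C under 100 µmol photons per square metre and second in 12 h of light with sunrise and sunset of 2 h, and the copepod culture held over 2000 Acartia in 25 L, taken through a sieve of 300 µm. The labels describe removal of ribosomal RNA, strand marking with dUTP and paired reads, and they name different models of the HiSeq instrument in the design text and in the protocol. The time between adding the filtered medium and sampling is not given in the sources used here. The labels do not say whether the cultures of a pair were grown apart from those of the other pairs, so p-values measure the spread between these libraries.

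The deposited data are 3 tables, each for 1 control and 1 grazing library. Their expression columns hold expected counts as made by the authors, that is, estimated fragment counts per gene without normalization, of which 95.0 to 95.9% are whole numbers. Their FPKM columns, per the file headers, hold fragments per kilobase of gene length scaled to library size, where the authors wrote 0.001 in place of 0. The deposited log2 ratio is the log2 of grazing FPKM over control FPKM, and recomputing it from those columns gave the same values within rounding. The deposited P-value column compares 1 library with 1 library by a test that is not stated, and the deposited mark of up or down follows the sign of the ratio. The deposited gene length is in bases. The submitters' processing notes name BWA, Bowtie, Bowtie2 2.2.5 and RSEM 1.2.12 without the role or order of each. The genome build is not given in the sources used here, so no coordinates are given. Totals implied by FPKM were 100.47 to 100.56% of the listed totals, so FPKM was scaled to about the sum of the listed counts. The share of sequenced fragments that reached the tables cannot be read from this.

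The tables were joined on the NCBI gene identifier. They held 10066, 10072 and 10119 genes, 10268 in any and 9869 in all 3, and the 399 genes missing from at least 1 table were taken as 0 there. These genes carried 0.024% of all counts. All 10268 identifiers were found among the 10398 genes of the reference list of names. No gene encoded in the chloroplast or the mitochondrion was in the tables, so the lists of those genomes and the scaling without organelle and ribosomal RNA genes were not run. The most abundant gene took 1.68 to 2.09% of a library's counts and the 10 most abundant took 10.1 to 12.0%. The pairing in the labels was checked on the counts. After removal of each group's mean, the 3 control and grazing libraries with the same number correlated at 0.377, 0.271 and 0.587 over 3263 genes, and the other combinations at -0.437 to 0.144. Without that removal, the chi-square per degree of freedom between 2 libraries was 5.32 in pair 1 and 5.94 in pair 3. It was 8.95 in pair 2, where grazing 2 lay nearer to control 1, at 5.65. The counts therefore back pair 2 less clearly than pairs 1 and 3.

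Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 7476. Libraries were scaled by TMM with factors of 0.94, 1.002 and 1.067 for control libraries 1 to 3 and 0.961, 0.952 and 1.089 for grazing libraries 1 to 3. The quasi-likelihood test was fitted with the pair number as a block, and p-values were adjusted by Benjamini and Hochberg over all genes tested with a threshold of 0.05. The fit had 2 residual degrees of freedom per gene, 30.1 prior degrees of freedom and a biological coefficient of variation of 9%. Adjusted p-values of single genes are from this fit unless another tool is named. Values in CPM, the usual scaling of counts to a common library size, are means over the 3 libraries of a group with their standard deviation. Log2 fold changes are grazing over control. Their standard error is the absolute change over the square root of the test's F statistic. With 30.1 prior against 2 residual degrees of freedom, it and the p-values rest mostly on the spread shared by all genes. They can understate a gene's own spread between pairs, as for FRE5, with an error of 0.17 and pair ratios of -0.14, -0.29 and -1.78. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists of at least 5 tested genes, with adjustment over the 28 lists that reached that size. Agreement of the pairs is the correlation across genes of the log2 ratios of TMM-scaled CPM with a prior count of 2. Genes whose expected count is not a whole number in at least 1 library were taken to share reads with other genes. They were 388 of the 7476 tested, 16 of the 151 called and 10 of the 126 named by the rule below.

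The model, the thresholds, the 30 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The lists were searched by words in gene symbols, product titles and orthology definitions. They cover light harvesting, photosynthetic electron transport, carbon fixation, pigment synthesis, nitrogen, phosphorus, iron, silicon and frustule, ribosomal proteins, ribosome assembly and translation factors, aminoacyl-tRNA synthetases, proteasome and ubiquitin, chaperones, redox, DNA replication and cell cycle, histones, cytoskeleton, fatty acid synthesis, lipid breakdown, oxylipin-related genes, glycolysis, the tricarboxylic acid cycle, mitochondrial electron transport, cell death, kinases and calcium signalling, the cell surface, transcription regulators, transposons, B vitamins and methionine, and membrane transporters. A gene can be in several lists. The rule named the 5 higher and 5 lower called genes with the largest absolute log2 fold change among those with the same sign in all 3 pairs and a mean count of at least 50, then 10 higher and 10 lower described genes by the same rule, of which 6 higher were available, and up to 4 members of each list with the smallest p-values. Any other gene is said to be chosen after its values were seen. Reads of copepods or bacteria have no gene in these tables, so their share was not analysed here.

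Alternatives were edgeR without the pair term, DESeq2 1.42.0, limma voom, RLE scaling, library size alone, no low-count filter, a mean count of at least 50, limma on log2 of FPKM plus 0.5 or plus 0.1, each pair left out, each library left out without the pair term, an adjusted p under 0.1, and an absolute log2 fold change of at least 1. For the lists they were camera with an estimated correlation and fry. Removal of a gene length trend with a lowess span of 0.3, thinning of all libraries to equal totals and the changed list searches were chosen after seeing the data. Tested on simulated data with 200 changed genes in each of 5 sets, the paired edgeR test recovered 39.6% of 1.5-fold, 78% of 2-fold, 97% of 3-fold and 99.6% of 4-fold changes, and 4% of its calls were false. Without the pair term it recovered 46.8% of 2-fold changes, and DESeq2 recovered 39.2%. The simulated counts were drawn independently for each gene from the paired fit's own means and dispersion trend. The 4% is therefore no estimate of false calls in the real data. Mean calls were 155 for paired edgeR, 101 for DESeq2 and 108 for edgeR without the pair term. The real data gave 151, 21 and 6, so the simulated sets do not resemble them in this respect. A list shifted by 0.3 on the log2 scale was called by camera with the preset correlation in 5 of 5 simulated sets and with an estimated correlation in 0 of 5. In 5 sets without a shift the mean number of lists called was 0.2 with the preset and 0 with the estimated correlation. Genes were drawn independently here too, so these sets cannot tell how either setting treats a list whose members vary together. The setting with an estimated correlation missed the planted shift each time, so a list it does not call is not shown to be unchanged.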

Results

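The series measured messenger RNA of the diatom Phaeodactylum tricornutum, a unicellular alga of coastal waters. In the grazing treatment a culture received medium in which copepods of the species Acartia tonsa, small crustaceans that eat diatoms, had been kept and from which animals and cells had been removed by a filter of 0.1 µm. In the control treatment a culture received the same amount of sterile-filtered seawater. There were 3 control and 3 grazing libraries, which the labels arrange as 3 pairs of 1 control and 1 grazing treatment. The deposited expected counts summed to 1235671, 1512723 and 1162462 in control libraries 1 to 3, and to 1157976, 880903 and 1018319 in grazing libraries 1 to 3. Between 9661 and 9964 genes had a count above 0 in a library. A floor of 3 counts corresponded to 1.98 to 3.41 CPM (counts per gene scaled to a common library size), an amount that covers counting error only.

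The first comparison asks which diatom genes differ in messenger RNA when the cells meet water that held grazers, with no grazer present. Of 7476 genes tested, 151 passed an adjusted p of 0.05 in the paired edgeR test, 135 of them lower and 16 higher with grazing. The lower side was less dominant among the 988 genes with an unadjusted p under 0.05, 593 lower and 395 higher, and the median over all tested genes was 4.3e-03 on the log2 scale. The median change was -0.62 on the log2 scale among the genes that fell and 0.70 among those that rose, and 13 genes fell by at least 1 on the log2 scale. The clearest fall was that of PHATRDRAFT_48096, a gene without a description, from 746 ± 83.5 to 323 ± 27.7 CPM (SD, n = 3 per group; log2 fold change -1.20 ± 0.10 SE, adjusted p = 5.16e-09, edgeR). Among single genes of known function, those for a CDC20 cofactor of mitosis, 3 small heat shock proteins, nitrate and nitrite reductase and the ferric reductase FRE5 fell, and those for the light-harvesting proteins Lhcf5 and Lhcf6 rose, though the lists they belong to did not pass as groups. Of these genes, only the CDC20 gene and the small heat shock gene HSP20B kept their calls without each pair in turn. The fall of FRE5 was concentrated in pair 3, and Lhcf5 was lower with grazing in pair 2.

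Genes of DNA replication and the cell cycle supplied 4 of the falls and 0 of the rises among 77 tested members, and the count adjusted over the list alone was also 4 lower and 0 higher. PHATRDRAFT_45416, which encodes the CDC20 cofactor that directs the anaphase-promoting complex to its targets in mitosis, fell from 514 ± 85.6 to 321 ± 105 CPM (SD, n = 3 per group; log2 fold change -0.71 ± 0.10, adjusted p = 9.6e-05, edgeR) and was lower in all 3 pairs. The cyclin gene dsCYC5 fell by 0.64 on the log2 scale (adjusted p = 0.0185), and the cyclin gene dsCYC7 fell by 0.44 (adjusted p = 0.0404), although dsCYC7 was slightly higher in pair 2, at 0.03, and its log2 fold change without that pair was -0.69. The annotation describes both as cyclin A, a match that was not checked further. As a group the list did not pass, with 44 of 77 members positive, a median of 0.05 and a camera adjusted p of 0.996. PHATRDRAFT_49277, which encodes the single-stranded DNA-binding replication protein A1, fell by 0.59 (adjusted p = 0.0142). Of the 14 histone genes tested 0 passed, and 9 had a positive change, with H2B-1b at 0.32 (adjusted p = 0.303). The call of PHATRDRAFT_45416 remained without each pair in turn, whereas dsCYC5 missed the threshold without pair 1 (adjusted p = 0.233) and without pair 2 (0.121), dsCYC7 without pair 1 (0.566, log2 fold change -0.25) and without pair 3 (0.186), and PHATRDRAFT_49277 without pair 1 (0.0518) and without pair 2 (0.135).

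Chaperone and heat shock genes supplied 4 falls and 0 rises among 50 tested members, and 5 lower and 0 higher when adjusted over the list alone. Small heat shock proteins hold unfolded proteins in solution. Of their genes, HSP20B fell from 790.5 ± 135 to 524 ± 171 CPM (SD, n = 3 per group; log2 fold change -0.62 ± 0.11, adjusted p = 0.00135, edgeR), HSP20C fell by 0.57 and HSP20 fell by 0.40. HSP70A, an abundant chaperone gene, fell by 0.42, from 1482 ± 72.1 to 1115 ± 140 CPM. All of them were lower in each of the 3 pairs. HSP20B kept its call without each pair in turn. HSP20C missed the threshold without pair 1 (adjusted p = 0.318) and without pair 2 (0.0787), HSP20 without pair 1 (0.239) and without pair 2 (0.156), and HSP70A without pair 1 (0.518, log2 fold change -0.28) and without pair 3 (0.0559). In the list of redox genes, 2 of 63 tested members rose and 1 fell, the same counts as when adjusted over the list alone. PHATRDRAFT_17427, a glutathione-dependent formaldehyde dehydrogenase gene, rose from 243 ± 9.59 to 322 ± 13.3 CPM, a log2 fold change of 0.41 ± 0.10 (adjusted p = 0.0203). The ascorbate peroxidase gene PHATRDRAFT_47395 rose by 0.92 ± 0.24 (adjusted p = 0.0375), and PHATRDRAFT_bd1645, which has a peroxidase domain, fell by 0.58 ± 0.11 (adjusted p = 0.00189). PHATRDRAFT_17427 missed the threshold without any one of the 3 pairs, at adjusted p of 0.096, 0.0921 and 0.0668, PHATRDRAFT_47395 without pair 1 (0.128) and without pair 3 (0.5), and PHATRDRAFT_bd1645 without pair 3 (0.0957).

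In nitrogen uptake and assimilation, 2 of 43 tested members fell and 0 rose, and the counts adjusted over the list alone were the same. They encode the consecutive enzymes that reduce nitrate to ammonium. The nitrate reductase gene PHATRDRAFT_54983 fell from 35.7 ± 18.3 to 16.7 ± 3.02 CPM (SD, n = 3 per group; log2 fold change -1.10 ± 0.25, adjusted p = 0.0142, edgeR), with log2 ratios of -1.19, -0.19 and -1.33 in pairs 1 to 3. The nitrite reductase gene PHATRDRAFT_27757 fell from 20.3 ± 6.95 to 9.18 ± 3.28 CPM (log2 fold change -1.15 ± 0.31, adjusted p = 0.0459), with log2 ratios of -1.37, -0.63 and -1.02. The ammonium transporter gene cc1 stood at 0.55 (adjusted p = 0.429) and the arginase gene PHATRDRAFT_38509 at 0.25 (adjusted p = 0.405, and 0.12 on the log2 scale without pair 3). Both reductase mRNAs were scarce, with mean counts of 30.7 and 17.5 per library. The call of PHATRDRAFT_54983 was lost without pair 1 (adjusted p = 0.083) and without pair 3 (0.305), and that of PHATRDRAFT_27757 without any one pair, at 0.261, 0.0787 and 0.277 without pairs 1, 2 and 3. The list of phosphorus uptake and scavenging genes had 0 of 25 tested members passing over all genes and 1 higher when adjusted over the list alone, the phosphate transporter gene PHATRDRAFT_17265 at 0.35 (adjusted p = 0.0745 over all genes). The silicon and frustule list had 4 tested members and 0 passing, with the silicon transporter gene Sit4 at 0.69 (adjusted p = 0.282) and the frustulin gene fru2 at -0.14.

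Of the iron uptake and storage genes 13 of 15 tested members had a negative change, but the list did not pass (camera adjusted p = 0.0854; adjusted p = 0.622 with an estimated correlation), and its median was positive in pair 3, at 0.08. FRE5, a ferric reductase gene, fell from 3531 ± 651 to 2227 ± 855 CPM (SD, n = 3 per group; log2 fold change -0.72 ± 0.17, adjusted p = 0.0185, edgeR), and the iron starvation induced gene ISIP1 fell by 0.45 ± 0.11 (adjusted p = 0.0285). Over the list alone 3 members passed, all lower, and over all genes 2. FRE3 at -0.66 (adjusted p = 0.175) and FRE2 at -0.40 (adjusted p = 0.271) missed the threshold over all genes. The fall of FRE5 was concentrated in pair 3, with log2 ratios of -0.14, -0.29 and -1.78, and its call was lost without that pair (log2 fold change -0.21, adjusted p = 0.716). ISIP1 lost its call without pair 1 (adjusted p = 0.0871) and without pair 2 (0.299, log2 fold change -0.29).

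Light-harvesting genes, which encode the fucoxanthin chlorophyll proteins of the diatom antenna, supplied 2 rises and 0 falls among 35 tested members, and 3 higher and 0 lower when adjusted over the list alone. Lhcf6 rose from 25.5 ± 7.28 to 43.8 ± 4.77 CPM (SD, n = 3 per group; log2 fold change 0.79 ± 0.21, adjusted p = 0.0404, edgeR). Lhcf5 rose from 320 ± 176 to 586 ± 391 CPM (log2 fold change 0.73 ± 0.20, adjusted p = 0.042), with log2 ratios of 0.68, -0.62 and 1.78 in pairs 1 to 3 and a log2 fold change of 1.21 without pair 2. Counts of both genes include reads split with other genes, as values that are not whole numbers show. Lhcf5 was not called without pair 3 (log2 fold change 0.15, adjusted p = 0.795), and Lhcf6 not without pair 2 (0.313) or pair 3 (0.11). Lhcf10, at 0.35 (adjusted p = 0.117, and 0.019 without pair 2), and Lhcr3, at 0.35 (adjusted p = 0.227), did not pass. Photosynthetic electron transport had 9 tested members, 0 passing over all genes and 1 higher when adjusted over the list alone, namely OEE3 of the oxygen-evolving complex at 0.48 (adjusted p = 0.133 over all genes). In pigment synthesis, 1 of 41 tested members passed, also when adjusted over the list alone, the uroporphyrinogen decarboxylase gene HemE_2 of the tetrapyrrole pathway, which fell by 0.82 ± 0.19 (adjusted p = 0.0168) and missed the threshold without pair 2 (0.246). The carbon fixation and concentration list had 8 tested members and 0 passing, with SBPase of the Calvin cycle at -0.12 (adjusted p = 0.884).

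Genes of the cell surface and of signalling were also among the falls. PHATRDRAFT_44339, which encodes a protein like the MNN10 subunit of the mannan polymerase that extends sugar chains on glycoproteins in yeast, fell from 97.4 ± 7.88 to 50.2 ± 0.325 CPM (SD, n = 3 per group; log2 fold change -0.95 ± 0.15, adjusted p = 0.00023, edgeR). It and the receptor-like gene PHATRDRAFT_1631, which fell by 0.69 (adjusted p = 0.0396), were the 2 lower members of 28 tested in the cell surface and polysaccharide list, with 0 higher, and the counts adjusted over the list alone were the same. In the kinase and calcium signalling list, 8 of 336 tested members fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone. That search also drew in many genes whose titles contain the words binding protein or containing protein. Lhcf5, PHATRDRAFT_23444 and PHATR_43850 have such titles, which do not by themselves place a gene in signalling. A stricter search chosen after seeing the data left 141 tested members, of which 3 fell and 0 rose. In the wider list the GTP-binding protein gene PHATRDRAFT_23444 fell by 1.69 ± 0.28, from 30.8 ± 7.52 to 9.37 ± 1.35 CPM (adjusted p = 0.000456), PHATRDRAFT_1196, similar to leucine-rich repeat receptor kinases, fell by 1.42 ± 0.31 (adjusted p = 0.00961), and PHATR_43850, with a CCT motif, fell by 0.63 ± 0.11 (adjusted p = 0.000746). PHATRDRAFT_44339, PHATRDRAFT_23444 and PHATR_43850 kept their calls without each pair in turn, but PHATR_43850 lost its call with DESeq2 and without the pair term. PHATRDRAFT_1196 missed the threshold without pair 2 (adjusted p = 0.146), and PHATRDRAFT_1631 without any one pair (0.161, 0.187 and 0.112).

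Among ubiquitin and proteasome genes 4 of 149 tested members fell and 0 rose, the same counts as when adjusted over the list alone. They encode the ubiquitin ligases PHATRDRAFT_45011, which fell by 1.62, and PHATRDRAFT_47912, which fell by 0.45, and the deubiquitinating enzymes PHATRDRAFT_47704, which fell by 0.69, and PHATRDRAFT_bd1763, which fell by 0.53. PHATRDRAFT_45011 missed the threshold without pair 3 (adjusted p = 0.213), PHATRDRAFT_bd1763 without pair 2 (0.152) and without pair 3 (0.471, log2 fold change -0.35), and PHATRDRAFT_47912 (0.0767, 0.0703 and 0.0659) and PHATRDRAFT_47704 (0.145, 0.0892 and 0.15) without any one pair. In the list of ABC and other membrane transporters 3 of 69 fell and 0 rose, and 5 fell when adjusted over the list alone. The members PHATRDRAFT_25217, PHATRDRAFT_11271 and PHATRDRAFT_46086 fell by 0.67, 0.60 and 0.54, and they missed the threshold without pair 1 (adjusted p of 0.137, 0.0582 and 0.239) and without pair 2 (0.197, 0.219 and 0.0852). PHATRDRAFT_46086 entered by the words ATP-binding cassette in its description, of subfamily F, which does not show that it is a transporter. In the list of B vitamins and methionine, 1 of 9 tested members passed, also when adjusted over the list alone. This was PHATRDRAFT_28056, the cobalamin-independent type of methionine synthase, which fell by 0.53 ± 0.12 (adjusted p = 0.0125, edgeR) and missed the threshold without pair 1 (0.143) and without pair 3 (0.163). METH, a cobalamin-dependent methionine synthase gene, stood at 0.11 (adjusted p = 0.711). In the cytoskeleton list 1 of 43 members passed, also when adjusted over the list alone, the actin gene ACT1, which rose by 0.70 ± 0.17 (adjusted p = 0.0193), shares reads with other genes and missed the threshold without pair 1 (0.17) and without pair 2 (0.154). Cell death genes had 0 of 5 passing over all genes, and 1 higher and 1 lower when adjusted over the list alone, with the metacaspase genes PHATRDRAFT_54872 at 0.65 (adjusted p = 0.107) and PHATRDRAFT_48151 at -0.55 (adjusted p = 0.156). Transcription regulators had 0 of 25 passing over all genes, and 1 higher and 1 lower when adjusted over the list alone, with E2F1 at -0.67 (adjusted p = 0.273).

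**Figure D1:**
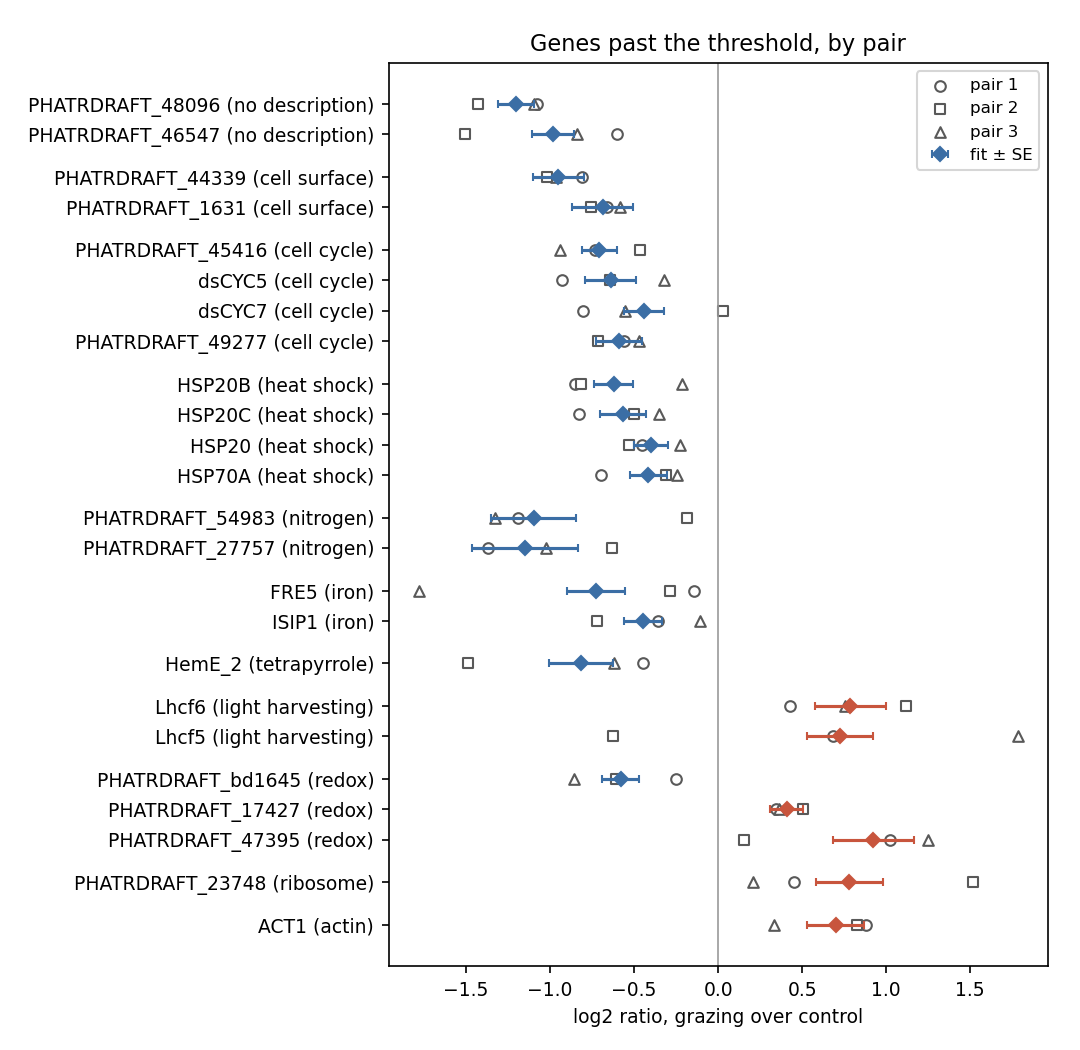
Log2 ratio of grazing over control for named genes that passed the test, with each pair as an open symbol and the fitted change as a diamond with its standard error, blue where lower and red where higher. PHATRDRAFT_48096 lies between -1.43 and -1.08 in the 3 pairs, while FRE5 lies at -0.14, -0.29 and -1.78. The standard error rests mostly on the spread shared by all genes and does not show that of the 3 pairs.

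A majority of the genes that changed have no description. They were 97 of the 151 called genes, or 64.2%, against 55.1% of all 7476 tested (two-sided Fisher's exact p = 0.0254), namely 90 of the 135 that fell (66.7%) and 7 of the 16 that rose (43.8%). Besides PHATRDRAFT_48096, the undescribed genes with the largest falls at a mean count of at least 50 were PHATRDRAFT_48827 (-1.10 ± 0.16, adjusted p = 6.5e-05, edgeR), PHATRDRAFT_49750 (-0.99 ± 0.18), PHATR_46827 (-0.99 ± 0.20) and PHATRDRAFT_46547, which fell from 1845 ± 526 to 909.5 ± 85.7 CPM (-0.98 ± 0.13, adjusted p = 1.52e-05). PHATRDRAFT_48827 and PHATRDRAFT_49750 share reads with other genes. The undescribed genes PHATRDRAFT_42608, PHATRDRAFT_47612 and PHATRDRAFT_bd1737 rose by 0.71, 0.54 and 0.54. Described genes that rose also include PHATRDRAFT_43627, an elongator complex subunit gene, by 0.46, PHATRDRAFT_44306, a protein phosphatase 2C gene, by 0.45, and PHATRDRAFT_43183, a transfer RNA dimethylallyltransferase gene, by 0.44. Described genes that fell also include those for a tyrosine transporter, PHATRDRAFT_45852 (-0.85), a potassium channel, PHATRDRAFT_bd1748 (-0.67), and an ABC transporter ATPase, PHATRDRAFT_45404 (-0.65). Of these genes, PHATRDRAFT_48096, PHATRDRAFT_48827, PHATRDRAFT_49750 and PHATRDRAFT_46547 kept their calls without each pair in turn, but the change of PHATRDRAFT_48827 was -0.69 without pair 2, and its call was lost with DESeq2 (adjusted p = 0.323), without the pair term (0.112) and with limma on log2 FPKM plus 0.5 (0.187) or plus 0.1 (0.198). PHATRDRAFT_46547 also lost its call without the pair term, and it and PHATRDRAFT_49750 with limma on log2 FPKM plus 0.5. DESeq2 gave PHATRDRAFT_49750 no adjusted p. Without pair 1 the threshold was missed by PHATRDRAFT_47612 (adjusted p = 0.474, log2 fold change 0.36), PHATRDRAFT_bd1737 (0.133), PHATRDRAFT_44306 (0.181), PHATRDRAFT_43183 (0.102) and PHATRDRAFT_45852 (0.0604). Without pair 2 it was missed by PHATR_46827 (0.104), PHATRDRAFT_42608 (0.226), PHATRDRAFT_47612 (0.0752), PHATRDRAFT_43627 (0.275), PHATRDRAFT_43183 (0.409, log2 fold change 0.27), PHATRDRAFT_45852 (0.0972), PHATRDRAFT_bd1748 (0.118) and PHATRDRAFT_45404 (0.127), and without pair 3 by PHATRDRAFT_bd1737 (0.16), PHATRDRAFT_43627 (0.195), PHATRDRAFT_44306 (0.333) and PHATRDRAFT_45404 (0.201).

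Of the 151 genes, 134 of those that fell and 15 of those that rose had the same sign in all 3 pairs, a property for which the paired test selects. The calls rest on the pairing, on the tool and on all 3 pairs. Without the pair term edgeR called 6 genes. With the pair term kept, DESeq2 called 21, limma on log2 FPKM called 1 and limma voom called 124. The paired edgeR fit called 93, 77 and 97 genes without pairs 1, 2 and 3. DESeq2 gave an adjusted p to 1509 genes only, and many of the 151 were not among them. Of the 151 genes, 69, 64 and 78 remained called in these 3 smaller fits, and 28 of them, all lower, in all 3 fits.

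The second comparison asks whether groups of genes with a shared function moved against the rest of the genome. Ribosomal protein genes did so in camera with its preset correlation only. Of 97 tested members 82 had a higher level with grazing, with a median log2 fold change of 0.20 and medians of 0.10, 0.11 and 0.32 in pairs 1 to 3 (camera, preset correlation of 0.01, adjusted p = 1.24e-06). With the correlation of the members taken from the data the call was lost (camera adjusted p = 0.595 with an estimated correlation). That setting called a list with a planted shift of 0.3 in 0 of 5 simulated sets. The redox list, with an estimated correlation of -4.4e-03, also went from an unadjusted camera p of 0.0213 to 0.0997. The loss therefore cannot be laid to the members' correlation alone. For the ribosomal list at the preset correlation, the camera adjusted p was 0.0225 without pair 3. Only 1 member passed as a single gene, also when adjusted over the list alone, PHATRDRAFT_23748 for ribosomal protein S28e, which rose from 39.1 ± 6.76 to 68.1 ± 26.5 CPM (SD, n = 3 per group; log2 fold change 0.78 ± 0.20, adjusted p = 0.0329, edgeR) and stood at 0.34 without pair 2 (adjusted p = 0.568). PHATRDRAFT_47804 for protein L37Ae stood at 0.67, PHATRDRAFT_22774 for L7e at 0.79 and PHATRDRAFT_30160 for S26e at 0.71, with adjusted p of 0.128, 0.133 and 0.167. Without pair 2 PHATRDRAFT_47804 stood at 0.31, and without pair 3 PHATRDRAFT_22774 stood at 0.41. Although the list was meant for cytosolic ribosomes, its search also took in members of the bacterial type found in plastids and mitochondria. The 75 tested genes of eukaryotic type had a median of 0.19 and 65 of them were positive, and the 19 of bacterial type had a median of 0.24 with 15 positive, though their median in pair 2 was -0.03. This division was chosen after seeing the data.

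Of 28 lists tested 1 passed camera, and 7 had an unadjusted p under 0.05. Those 7 were the ribosomal list and 6 that missed the adjusted threshold. Iron uptake and storage had a median of -0.26 (adjusted p = 0.0854). The positive medians were those of glycolysis and gluconeogenesis at 0.07 (adjusted p = 0.0854), redox genes at 0.12 (0.149), mitochondrial electron transport and ATP synthase at 0.08 (0.158), light harvesting at 0.06 (0.158) and photosynthetic electron transport at 0.15 (0.188). In pair 3 the median of the iron list was 0.08, and without pair 3 this list passed as well (camera adjusted p = 7.55e-05). With an estimated correlation 0 lists passed (smallest adjusted p = 0.595), a setting that also called a planted list in 0 of 5 simulated sets. The test fry, which asks whether a list's genes move one way and does not compare them with other genes, called 0 lists (smallest adjusted p = 0.163).

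Several lists of central metabolism had no member that passed, over all genes or adjusted over the list alone. Among glycolysis genes, 0 of 49 passed and 32 were positive, with GPI_3, a glucose-6-phosphate isomerase gene, at -0.37 (adjusted p = 0.0589, edgeR) and the plastid aldolase gene FbaC1, which shares reads, at 0.32 (adjusted p = 0.0872). Mitochondrial electron transport had 0 of 24 passing and 17 positive, with the complex I gene PHATRDRAFT_28620 at 0.42 (adjusted p = 0.225). The tricarboxylic acid cycle had 0 of 31 passing and a median of 0.07 (camera adjusted p = 0.247), with the malate dehydrogenase gene MDH at 0.22. Aminoacyl-tRNA synthetases had 0 of 44 passing, a median of 0.08 (camera adjusted p = 0.229) and PHATRDRAFT_21513 for valine at 0.29. Fatty acid synthesis and desaturation had 0 of 28 passing and a median of -0.05 (camera adjusted p = 0.833), with the thiolase gene KCT1, also a member of the lipid breakdown list, at -0.54 (adjusted p = 0.303). The search for this list also took in phytoene genes of pigment synthesis, such as PDS1 at 0.49 and PDS2 at -0.57. Lipid breakdown had 0 of 33 passing, and the oxylipin-related list, named for the defence compounds that some diatoms make from fatty acids, had 0 of 7 passing, with the lipase gene PHATRDRAFT_45518, a member of both, at -0.26 (adjusted p = 0.245). Ribosome assembly and translation factors had 0 of 104 passing, with PHATRDRAFT_27956 for elongation factor G at 0.58 (adjusted p = 0.244).

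For the remaining lists camera gave adjusted p of 0.229 for chaperones (median -0.02), 0.257 for histones (0.18), 0.277 for the cell surface (-0.06), 0.783 for nitrogen (-0.04), 0.957 for pigment synthesis (0.03) and 0.957 for the cytoskeleton (0.01). It gave 0.996 for kinases and calcium signalling (-0.01), cell death (-0.02), DNA replication and the cell cycle (0.05), ribosome assembly (0.03), lipid breakdown (0.01), the oxylipin-related list (-0.01), phosphorus (-9e-04), B vitamins and methionine (0.08), membrane transporters (0.01), transcription regulators (-0.01), ubiquitin and the proteasome (-0.01) and carbon fixation (-0.04). The sign of the median, the mean and the test differed in 7 of these. Means were -0.02 for ribosome assembly and -0.02 for transporters, where median and test pointed up, 0.03 for carbon fixation and 0.01 for the oxylipin-related list, where the median was negative and the test pointed up, -0.01 for lipid breakdown and -0.03 for B vitamins, where the median was positive and the test pointed down, and, for transcription regulators, -2.1e-03 with a test that pointed up. The transposon list had 1 tested member, PHATR_46847, at 0.30 (adjusted p = 0.518), and with the silicon list it was too small for camera.

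**Figure D2:**
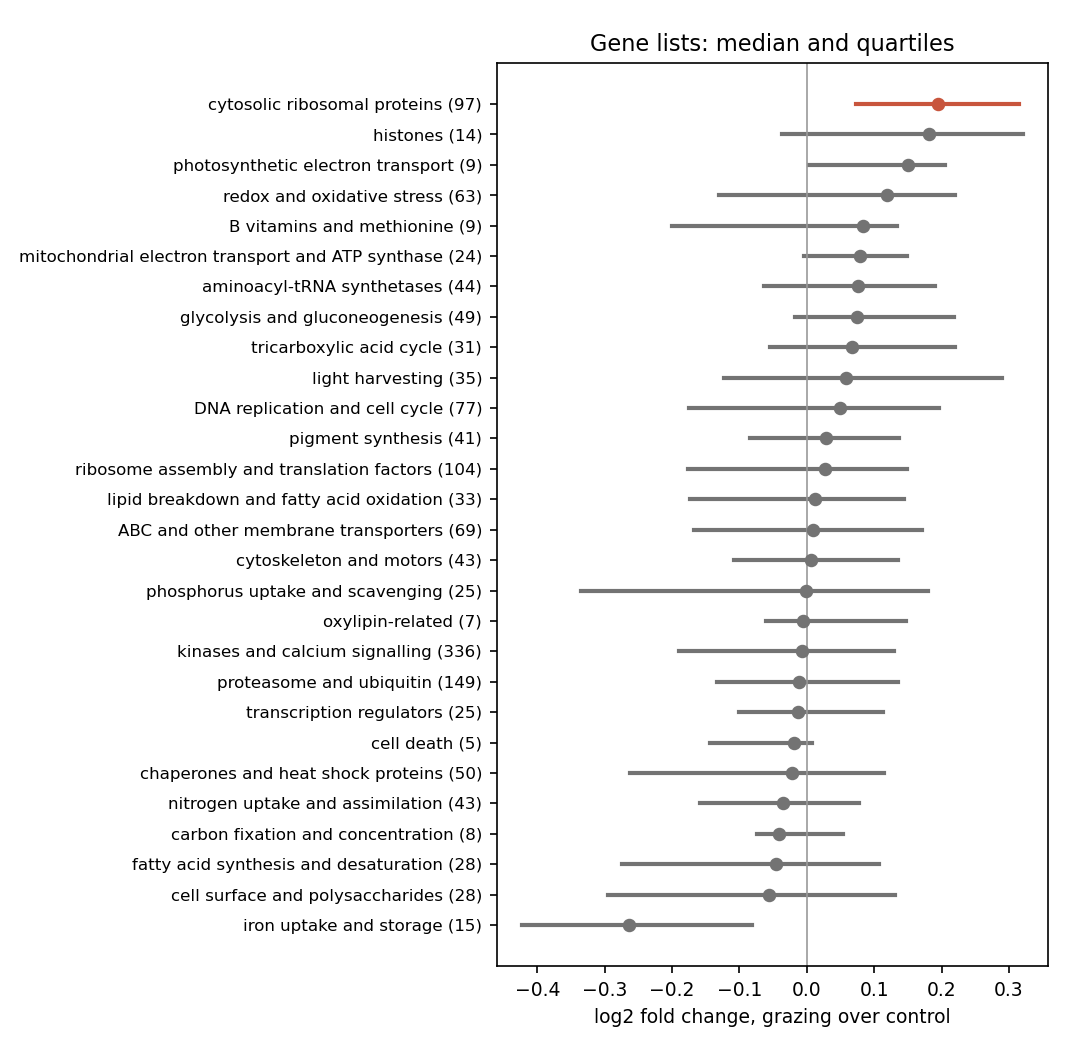
Log2 fold change of grazing over control in each gene list, with the median of the tested members as a point, their quartiles as a bar and their number in parentheses. The ribosomal protein list, in red, has a median of 0.20 and passed camera with the preset correlation only, and the iron list has a median of -0.26.

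The third comparison asks how far the 3 pairs show the same response. Over 7476 genes the log2 ratios of 2 pairs correlated weakly, with Pearson coefficients of 0.082 for pairs 1 and 2, 0.157 for pairs 1 and 3 and 0.142 for pairs 2 and 3, a mean of 0.127. Spearman coefficients were 0.135, 0.184 and 0.137, and the share of genes with the same sign was 55.5%, 57.2% and 54.8%. These are coefficients across genes, which are not independent replicates, so no p is given. Among the 3263 genes with a mean count of at least 50 the Pearson coefficients were 0.262, 0.323 and 0.307. The leading principal component carried 39.5% of the variance and set control 3 and grazing 3, at 12.17 and 10.49, apart from the other 4 libraries, at -7.94 to -2.35. The next component, with 24.2%, had the control libraries at 4.74 to 8.84 and the grazing libraries at -7.36 to -5.14. Single genes also differed between pairs. The iron starvation induced gene ISIP2A, chosen after its values were seen, had log2 ratios of -0.04, -0.18 and 1.64 (adjusted p = 0.31, edgeR), and it passed without pair 1 (adjusted p = 0.0121).

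**Figure D3:**
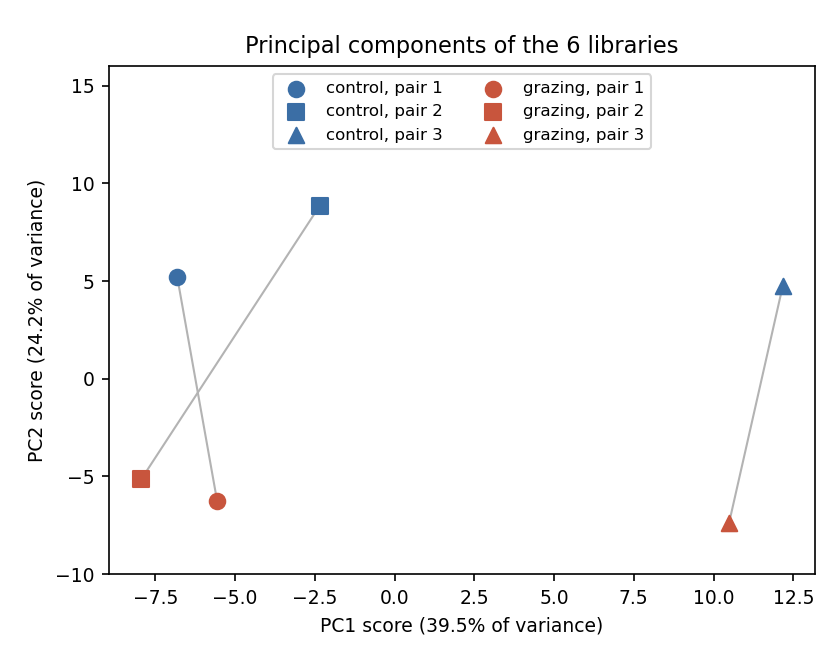
Scores of the 6 libraries on the first 2 principal components of log2 CPM, with 39.5% and 24.2% of the variance on the axes and a line joining each pair. Pair 3 lies apart on the horizontal axis, and the 3 grazing libraries lie below the 3 control libraries on the vertical axis.

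The last comparison describes the deposited tables, each of which compares 1 control with 1 grazing library without replicates. Their marks of up or down follow the sign of the log2 ratio alone and cover 5301 genes up and 4757 down in pair 1, 4226 and 5844 in pair 2, and 5266 and 4834 in pair 3, in total 30228. With the deposited p-values adjusted by Benjamini and Hochberg to at most 0.001 and an absolute log2 ratio of at least 1, the counts were 3 up and 15 down, 5 up and 27 down, and 10 up and 6 down. Pairs 1 and 2 shared 3 genes down, where independent lists would share 0.0408, pairs 1 and 3 shared 1 (0.00903 for independent lists) and pairs 2 and 3 shared 1 (0.0163). Of the genes up, pairs 2 and 3 shared 2 (0.00452 for independent lists) and the other combinations 0. Genes marked in opposite directions numbered 4 for pairs 1 and 2 (0.0157 for independent lists), 2 for pairs 1 and 3 (0.0169) and 0 for pairs 2 and 3 (0.0301). A single gene was down in all 3 tables, PHATRDRAFT_48096, with deposited log2 ratios of -1.05, -1.51 and -1.07, and 0 were up in all 3. Absolute log2 ratios of at least 2 numbered 274 up and 335 down in pair 1, 160 and 546 in pair 2, and 252 and 295 in pair 3, and in 472, 521 and 399 of them 1 of the counts was 0.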

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

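The removal of a gene length trend, the thinning to equal totals and the changed list searches were chosen after seeing the data. The count of 151 genes came to 6 without the pair term, 21 with DESeq2 (of 1509 genes with an adjusted p), 1 with limma on log2 FPKM plus 0.5 and 1 on log2 FPKM plus 0.1, 86 after thinning to equal totals and 13 with an absolute log2 fold change of at least 1. It ranged from 0 to 97 when libraries were left out: 77 to 97 without 1 pair, with the lowest value without pair 2, and 0 to 19 without 1 library and without the pair term, with 0 without control 2 or grazing 2 and 19 without control 1. Thinning has fewer counts by its construction, the larger fold change is a stricter threshold and the fits without 1 pair have fewer libraries. The fits without 1 library also lack the pair term, and for them and the other settings the cause was not tested. The remaining 7 alternatives gave counts within 1.5 times, from 124 with limma voom to 224 at an adjusted p under 0.1. In each alternative with any call more genes were lower than higher. The 1 list that passed became 0 with an estimated correlation and 0 with fry, 1 to 2 without 1 pair, with the iron list added without pair 3, and 2 with the length trend removed, where glycolysis was added; the cause was not tested. The mean correlation of the pairs, 0.127, was 0.297 at a mean count of at least 50 and 0.168 with a prior count of 10, both of which give less weight to scarce genes, and 0.0824 to 0.157 without 1 pair. The 30228 deposited marks became 66 with adjusted p of at most 0.001 and an absolute log2 ratio of at least 1, 1862 with an absolute log2 ratio of at least 2, and 20128 to 20170 without 1 table. Among the genes the text names the sign turned for ISIP2A, which is not called, from 0.41 to -0.029 without the pair term, and it ranged from -0.11 to 0.74 without 1 pair, with the lowest value without pair 3; the cause was not tested. The scaling without organelle and ribosomal RNA genes was not run, since the tables hold none. With 3 pairs and 880903 to 1512723 counts per library, small changes and genes with few counts are the least likely to pass. In simulated data 39.6% of 1.5-fold changes were recovered. Those sets did not resemble the real data in the calls of the other tools, so this is no measure of the power here, and recovery by count was not measured.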

Other observations

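The tests chosen only after their result was seen are thinning to equal totals, the ribosomal medians per pair, the ribosomal list in other splits, the nitrate transporter median and the count of neighbouring genes. Some genes outside the lists, chosen here after their values were seen, also fell with grazing (paired edgeR, lower in all 3 pairs). They are single genes, with no test of a group. PHATRDRAFT_30461, which encodes 7-dehydrocholesterol reductase of sterol synthesis, fell by 0.44 on the log2 scale (adjusted p = 0.0282), PHATR_41807, the serine palmitoyltransferase that opens sphingolipid synthesis, fell by 0.41 (adjusted p = 0.0376), and PHATRDRAFT_54257, the ethanolamine-phosphate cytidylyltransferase of phosphatidylethanolamine synthesis, fell by 0.47 (adjusted p = 0.0142). The uridine kinase gene PHATRDRAFT_43766 stood at -1.10 (adjusted p = 0.00467) and the apyrase gene PHATRDRAFT_45377 at -0.59 (adjusted p = 0.0142). The proline dehydrogenase gene PHATR_13232 fell by 0.52 (adjusted p = 0.0318) and the inositol oxygenase gene PHATRDRAFT_45657 fell by 0.38 (adjusted p = 0.0422). Each missed the threshold without 1 pair or more: PHATRDRAFT_30461 without pair 1 (0.42) and pair 2 (0.0865), PHATR_41807 without any one (0.096, 0.19 and 0.16), PHATRDRAFT_54257 without pair 1 (0.182) and pair 2 (0.145), PHATRDRAFT_43766 without pair 2 (0.0719), PHATRDRAFT_45377 without pair 1 (0.235), PHATR_13232 without pair 2 (0.22) and pair 3 (0.201), and PHATRDRAFT_45657 without pair 2 (0.19) and pair 3 (0.326).

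The next 4 genes were chosen in the same way. PHATRDRAFT_45968, which encodes the SSRP1 subunit of the histone chaperone FACT, fell by 0.46 (adjusted p = 0.0115), and PHATRDRAFT_44761, the elongation factor SPT5, fell by 0.41 (adjusted p = 0.0321). MYT1, a member of the kinase list similar to wee1, which restrains entry into mitosis, fell by 0.41 (adjusted p = 0.0276), and PHATRDRAFT_23629, a calcium pump of the endoplasmic reticulum, fell by 0.54 (adjusted p = 0.0142). PHATRDRAFT_45968, PHATRDRAFT_44761 and MYT1 missed the threshold without pair 1 (0.146, 0.307 and 0.195) and without pair 3 (0.131, 0.271 and 0.303), and PHATRDRAFT_23629 without pair 3 (0.427, log2 fold change -0.30). Called genes were neighbours on a chromosome in 6 cases, with both members lower in all 6, among them PHATRDRAFT_49735 and PHATRDRAFT_23444 at -0.96 and -1.69. Random sets of 143 of the 7251 tested genes on numbered chromosomes had a mean of 2.08 such cases over 10000 sets (one-sided permutation p = 0.0174).

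Called genes were lower more often than higher, 135 to 16. Lower totals of the grazing libraries may produce such an excess, yet after thinning to equal totals 91.9% of the calls (79 of 86) were still lower, where equal numbers were to be approached if depth were the cause. A choice of scaling may do so too, and an added shift of 0.1 on the log2 scale would bring 63 higher and 60 lower calls. The median change over all genes differed by at most 0.014 between the scalings tried, so among them none accounts for the excess. A fall of total mRNA cannot be seen in relative counts, and the biological explanation, a response to the medium of copepods, stays open as a hypothesis.

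The ribosomal protein list passed camera as higher with grazing, but not with an estimated correlation (adjusted p = 0.595) or fry (adjusted p = 0.303). The setting with an estimated correlation also called a planted list in 0 of 5 simulated sets, so its loss of the call decides nothing. Short genes moving together are argued against, since of 10000 random lists matched on length and mean count 0 reached the list's median of 0.20, a share of at most 0.01%, the smallest these draws can give, and the highest matched median was 0.14. A single pair as the source stays open and cannot be told apart from a change in all 3, since the list's median less that of all genes was 0.11 ± 0.13, 0.11 ± 0.14 and 0.32 ± 0.14 in pairs 1 to 3 (SE widened by the members' estimated correlation of 0.121). The call leaned most on pair 3. At the preset correlation the camera adjusted p was 0.0225 without pair 3, 1.09e-06 without pair 1 and 5.35e-07 without pair 2. Regroupings of the libraries that measure 1 pair called the list for pair 3 and not for pair 1 or pair 2. Members that vary together between any cultures remain a candidate explanation: 2 of the 3 other splits of the libraries that part all pairs also called the list, at adjusted p of 0.00114 and 0.00527 against 1.24e-06 for the real split, and 1 did not (0.789). Those splits carry part of the real difference, so this cannot be told apart from an effect of grazing.

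Nitrate and nitrite reductase genes were lower with grazing. A fall of nitrate uptake and reduction as a whole may be proposed, but the 4 tested nitrate transporter genes had a median of -0.15 (range -0.32 to 0.03, 2 positive, 0 called by edgeR). The standard error of their mean across genes was 0.10. These values lie far from the -1.10 and -1.15 of the reductases, which drew notice because they passed the threshold. The 8 tested ammonium transporter genes had a median of -0.05 and a range of -0.50 to 0.55. Both reductases had low counts, and their calls were lost in some or all of the fits without 1 pair, so a lower expression of this step in response to the copepod medium is a hypothesis for further measurement.

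There are 10 splits of the 6 libraries into groups of 3, too few for a share under 0.05. For the count of genes 1 of the 10 splits, the real one, reached 151, and the highest other had 3; the 3 others that part all pairs called 0 to 2 genes, and the 6 that part 1 pair called 0 to 3. With the pair term those 6 splits measure the real difference of a single pair, each pair in 2 of them, so they are not groupings unrelated to grazing. For the count of lists 8 of the 10 splits reached the real value of 1, and the highest other was also 1. Of the 4 splits that part all pairs, the real one included, 4 called 1 list, the iron list or the ribosomal list.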
